A study of Marchantia polymorpha with 8 samples.

How the data were processed

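RNA of *Marchantia polymorpha* Tak-1 and Mpcoi1 plants treated with C20 or mock was measured on 8 arrays of 1 slide, with both treatments of a replicate on the same array. Per the labels, plants grew for 3 weeks on Gamborg B5 medium with 1% agar, tissue was apical fragments without gemma cups, and amplified RNA made from 200 ng of total RNA was labelled with Cy3 and Cy5. The labels write the genotype of the Cy3 sample of the Tak-1 arrays as Tak1-1, which was read as Tak-1. Each array gives 1 ratio per gene, and the 4 arrays of a genotype are separate biological replicates.

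The deposited scanner files, made with Feature Extraction 10.7.3.1, hold mean and median pixel intensity of each spot and of its local background without correction, and per the file headers also processed intensity values after spatial detrending of background and linear and lowess dye normalization. Their deposited ratio column is the log10 of red over green processed signal and is 0 on dim spots with surrogate values. Other deposited columns are flags of 0 or 1 for spots well above background, saturated or uneven. The deposited value table holds log2 ratios turned to C20 over mock by the authors, whose normalization is not stated; against the ratios computed here r lay between 0.992 and 0.997. Gene models carried Mapoly identifiers, 12145 of 19217 with an Arabidopsis match. The gene list supplied with the work held 0 of these identifiers, so that no positions are given.

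Mean signals were corrected with the local median background by the normexp method with offset 50, and ratios were normalized by loess within each array, with limma 3.58.1 in R 4.3.3 and version 1.17.8 of the data.table package. Outlier spots, between 52 and 422 per array, were set to missing, and spots of a probe were averaged. A probe was tested if well above background on at least 3 of 4 arrays in at least 1 of the 4 groups of genotype and treatment, which left 20292 of 40422 probes. Each gene was represented by its brightest tested probe, for 10606 genes. Counts of arrays above background are those of the probe of a gene with the highest count, unless a probe is named. Of 8988 genes with more than 1 tested probe, 7 had probes called in opposite directions in Tak-1. Of 126 genes named in the text with another tested probe, 12 had one whose C20 effect differed by log2 1 or more from that of the brightest probe in either genotype.

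The C20 effect of each genotype and their difference came from a limma fit over all 8 arrays with a dye term, with 5 residual and 4.37 prior degrees of freedom. Mock Mpcoi1 was compared with mock Tak-1 by the separate-channel fit of limma after loess and Aquantile normalization, with an intraspot correlation of 0.463, for 10542 genes. P-values were adjusted by the Benjamini-Hochberg method over the genes tested. Genes with an adjusted p under 0.05 were called, and those with an absolute log2 value of at least 1 were counted as well. Where a group was above background on 0 arrays, the change of a gene is given as the measured fold of its brightest probe. A rule to replace each signal of such a group by the lowest signal called above background in that channel, where higher, changed none of these folds. They are therefore not lower bounds.

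Gene lists were made from keywords of the descriptions before the data were examined, and 25 of 28 held at least 3 tested genes. They were tested by camera with a correlation between genes of 0.01, adjusted over lists in each comparison, and again with an estimated correlation. Polyphenol oxidases and sulfotransferases had too few tested genes, and the oil body list held MpMYB02 (Mapoly0006s0226) alone, since MpC1HDZ (Mapoly0003s0030) was not tested. Named genes followed a fixed rule: fixed identifiers; described genes past the threshold with the same sign on all 4 arrays (or no overlap between genotypes), the 12 largest rises and 8 largest falls in Tak-1, 8 and 6 in Mpcoi1 and for the difference, 8 and 8 in mock; and the 3 members with the smallest p of every list that passed or had at least 2 called members. The rule gives 226 genes, of which the text names 129, a choice made after their values were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

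Alternatives fixed beforehand were Agilent's ratios, no background subtraction, offset 16, median pixel signal, median centring, scaling between arrays, no filter or a strict filter on dim probes, no dye term, arrays of each genotype alone, a block for replicate number, leaving out each array, a trended and robust variance, other summaries of probes, the value table and an adjusted p under 0.01. For mock they were Agilent's signals with quantile normalization, a common median, the mean of both channels and mock channels alone. Filters to genes above background in both genotypes were chosen after seeing the data. The fits were tested on simulated normalized values with 200 changed genes and noise independent between genes. They recovered 100%, 100%, 97.0% and 97.0% of changes of log2 1 in Tak-1, Mpcoi1, the difference and mock, and 95.5%, 94.0%, 79.1% and 86.6% of changes of log2 0.5, with 11, 4, 5 and 5 false calls among 208, 200, 189 and 194. Background correction, normalization, filters and the choice of probes were not simulated, nor were as many changes as the 4633 genes called in Tak-1.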

Results

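Transcript levels were measured in *Marchantia polymorpha*, a liverwort whose haploid plant body is used to study how land plants perceive hormones. The plants were the male wild-type accession Tak-1 and the mutant Mpcoi1, which carries a lesion in MpCOI1, the F-box receptor through which plants perceive jasmonate-type oxylipin hormones. Plants of each genotype received a treatment that the labels call C20 or a mock treatment, and were frozen 2 h later. The labels give no structure or dose for C20, and the design note of the series speaks of wounding where the sample labels give C20. Each genotype had 4 biological replicates of 18 plants each, and each replicate was a 2-colour Agilent array that carried C20 RNA in a dye and mock RNA in the other. C20 was in Cy5 in replicates 1 and 2 and in Cy3 in replicates 3 and 4. The series title places the work in the jasmonate pathway. The comparisons ask which transcripts C20 changed, whether that change differed without a working MpCOI1, and how the genotypes differed in mock.

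The array held 40422 probes for 19217 gene models, and 10606 genes had a probe well above background in enough arrays to be tested. The share of spots well above background lay between 38.0% and 42.9% in Cy3 and between 39.9% and 50.3% in Cy5 on Tak-1 arrays. On Mpcoi1 arrays it lay between 43.0% and 47.3% in Cy3 and between 51.0% and 54.2% in Cy5. No spot was saturated. Of 261 groups of 4 array values of the named genes, 15 held a value far from the other 3, where 13.05 would be expected by chance. Log ratios of C20 over mock correlated across genes with r between 0.896 and 0.950 within Tak-1, between 0.804 and 0.905 within Mpcoi1 and between 0.742 and 0.855 across genotypes. The number of arrays limits the precision of every value. Genes are given by their identifier on the array and by the description of their best Arabidopsis match, and values are log2 differences ± SE from limma over 4 arrays per genotype.

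The targeted gene was dim. The brighter of 2 tested probes of MpCOI1 (Mapoly0025s0025) was above background on 3 of 4 mock channels in Tak-1 and 1 of 4 in Mpcoi1. Its level in mock was 7.09 ± 0.27 (SD, n = 4) in Tak-1 and 6.47 ± 0.13 in Mpcoi1 on the log2 scale. The other probe, above background on 3 of 4 mock channels in each genotype, was at 6.91 ± 0.15 and 6.57 ± 0.10. The log2 difference of the brighter probe in mock, near the detection limit in Mpcoi1, was -0.63 ± 0.14 (limma adjusted p = 9.3e-03). The labels do not say where the lesion lies relative to the probes, so this level does not check the genotype labels. MpJAZ (Mapoly0097s0021) is the single JAZ repressor of this liverwort and an early transcriptional target of the pathway. Its level was 9.04 ± 0.33 (SD, n = 4) in mock Tak-1 and 7.65 ± 0.14 in mock Mpcoi1. The log2 difference was -1.39 ± 0.13 (adjusted p = 2.0e-05).

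In Tak-1, most of the largest rises with C20 among described genes were of small heat shock proteins, and most of the largest falls were of alpha carbonic anhydrases. The plastid chaperone HSP21 (Mapoly0045s0146) rose by 7.18 ± 0.10 on the log2 scale (adjusted p = 9.2e-11). The HSP17.6A match Mapoly0010s0142 rose by 6.72 ± 0.11, and the HSP20-like chaperones Mapoly0076s0004 and Mapoly0076s0003 by 6.66 ± 0.10 and 6.38 ± 0.10. The transcriptional coactivator MBF1C (Mapoly0105s0012), a regulator of heat tolerance, rose by 5.92 ± 0.10. Ranked among described genes with the same direction on all 4 arrays, the remaining members of the 12 largest rises were further small heat shock proteins (Mapoly0010s0143, Mapoly0022s0113, Mapoly0076s0006, Mapoly0010s0145, Mapoly0010s0141, Mapoly0076s0005 and Mapoly0045s0084), with rises between 5.21 and 6.24. Mapoly0076s0003, Mapoly0010s0145, Mapoly0076s0005 and Mapoly0076s0006 were above background on 2 of 4 mock arrays and Mapoly0076s0004, Mapoly0010s0141 and Mapoly0022s0113 on 3. Among the 8 largest falls ranked in the same way, 5 were alpha carbonic anhydrases, enzymes that interconvert carbon dioxide and bicarbonate. They were led by Mapoly0012s0062 at -3.65 ± 0.16 (adjusted p = 4.8e-08) and Mapoly0012s0068 at -3.43 ± 0.14. Mapoly0012s0070, Mapoly0012s0067 and Mapoly0012s0063 were at -3.13, -3.04 and -2.69. The other 3 falls were an early nodulin-like protein (Mapoly0130s0040, -2.62 ± 0.18), a leucine-rich repeat protein (Mapoly0020s0097, -2.38 ± 0.11) and a receptor-like kinase matching BAM3 (Mapoly0120s0050, -2.27 ± 0.09). These values are those of the brightest probe, and other probes of Mapoly0076s0004, MBF1C and Mapoly0022s0113 gave 4.95, 2.14 and 3.06. Other probes of the anhydrases Mapoly0012s0062, Mapoly0012s0067 and Mapoly0012s0068 gave -2.53, -1.44 and between -1.53 and -1.02. The probes of the 12 small heat shock proteins named in this text shared at most 26 of 60 bases. The probes of 6 alpha carbonic anhydrases formed 5 groups, with up to 54 of 60 bases shared, so their levels may not be separate.

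Gene lists of chaperones, glutathione transferases, transporters and WRKY or NAC factors, fixed beforehand from the annotation, passed their test upward at a preset correlation. For comparison, of all 10606 tested genes 2642 rose and 1991 fell in Tak-1. Of 127 tested heat shock proteins and chaperones, 69 rose and 12 fell, 70 and 13 when adjusted over the list alone, and 37 rose at least 2-fold (camera adjusted p = 1.4e-07; adjusted p = 0.149 with an estimated correlation). Of 76 glutathione transferases and thiol redox proteins, which conjugate and reduce electrophiles and peroxides, 32 rose and 10 fell, 34 and 11 adjusted over the list alone (adjusted p = 0.00568; adjusted p = 0.149 with an estimated correlation). The glutathione transferases Mapoly1812s0001 and Mapoly0177s0013 rose by 4.95 ± 0.08 and 4.12 ± 0.07. Mapoly0031s0032, not well above background on any mock array, rose 7.41-fold by its brightest probe (limma adjusted p = 2.6e-09). The other probe of Mapoly0031s0032 gave a smaller rise of 2.41 on the log2 scale. Folds given for single genes have a group in which no array was above background. They are measured folds of the brightest probe, not lower bounds. Of 37 ABC and MATE transporters, which export metabolites and xenobiotics, 17 rose and 5 fell, 18 and 6 adjusted over the list alone (adjusted p = 0.00603; adjusted p = 0.149 with an estimated correlation). PDR7 (Mapoly0176s0013) rose by 3.73 ± 0.07, MRP10 (Mapoly0032s0013) by 2.10 ± 0.07 and PDR6 (Mapoly0123s0008) by 1.84 ± 0.05. Of 17 WRKY and NAC transcription factors, which act in stress and defence, 14 rose and 2 fell, 14 and 3 adjusted over the list alone (adjusted p = 9.9e-04; adjusted p = 0.157 with an estimated correlation). The WRKY20 matches Mapoly0008s0159 and Mapoly0036s0129 rose by 2.18 ± 0.07 and 1.48 ± 0.05 and the NAC028 match Mapoly0020s0051 by 1.44 ± 0.07.

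Some oxylipin, jasmonate signalling and dirigent genes rose as well. Of 21 oxylipin biosynthesis genes, 14 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.00568; adjusted p = 0.157 with an estimated correlation). The 12-oxophytodienoate reductase OPR1 (Mapoly0097s0082) rose by 4.13 ± 0.13 and the acyl-CoA oxidase ACX1 (Mapoly0169s0009) by 0.81 ± 0.05, whereas the lipoxygenase LOX1 (Mapoly0063s0014) fell by 1.87. All 3 jasmonate signalling genes rose, also when adjusted over the list alone (adjusted p = 0.0392; adjusted p = 0.317 with an estimated correlation). The rises were 1.28 ± 0.10 for MpJAZ, 0.69 ± 0.06 for TIFY8 (Mapoly0079s0053) and 0.25 ± 0.06 for NINJA (Mapoly0005s0166), an adaptor of JAZ repressors. Of 25 dirigent proteins, which guide the coupling of phenoxy radicals, 15 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.00637; adjusted p = 0.157 with an estimated correlation). Rises were 5.11 ± 0.10 for Mapoly0117s0014, 4.63 ± 0.14 for Mapoly0117s0013 and 3.23 ± 0.08 for Mapoly0117s0016. The haem peroxidase and cell wall lists passed their test downward, which compares values rather than calls. Of all 10606 tested genes 2642 rose and 1991 fell. The share of peroxidases that fell was smaller than that, and their log2 median was -0.12 against -0.00 for all tested genes. Of 126 peroxidases 9 rose and 15 fell, 9 and 11 adjusted over the list alone (adjusted p = 0.0207; adjusted p = 0.681 with an estimated correlation). Mapoly0057s0094 was at -1.68 ± 0.06, but Mapoly0040s0117 and Mapoly0076s0031 were at 2.64 ± 0.10 and 1.46 ± 0.05. Of 76 cell wall genes 10 rose and 20 fell, 10 and 19 adjusted over the list alone (adjusted p = 0.0392; adjusted p = 0.209 with an estimated correlation). The xyloglucan endotransglucosylase XTH5 (Mapoly0040s0062) and the pectin lyase-like Mapoly0004s0080 rose by 1.86 ± 0.06 and 2.33 ± 0.08, the latter above background on 2 of 4 mock arrays and at 0.60 with its other probe.

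In the test across genes, 4633 of 10606 genes changed in Tak-1, 2642 up and 1991 down, and 651 rose and 172 fell at least 2-fold. At an unadjusted p under 0.05 the number was 5327. The balance of directions depended on scaling: Agilent's own log ratios gave 2231 up and 3206 down, 2038 and 3538 came from the deposited value table, and median centring 1595 and 1976. The log2 median of all tested genes was -0.00 here, -0.10 with Agilent's ratios and -0.11 with median centring, so small changes hold only relative to that median. Of the reference genes fixed beforehand, actin MpACT7 (Mapoly0016s0139) and MpEF1a (Mapoly0024s0116) stood at 0.09 ± 0.06 and 0.04 ± 0.05 in Tak-1, and MpAPT (Mapoly0100s0027) at 0.21 ± 0.06 (adjusted p = 0.025). The calls of MpAPT and MpCOI1 in Tak-1 were lost without replicate 1 (0.12 and -0.30) and without replicate 4 (0.22 and -0.21), and that of MpCOI1 also without replicate 2 (-0.28).

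**Figure D1:**
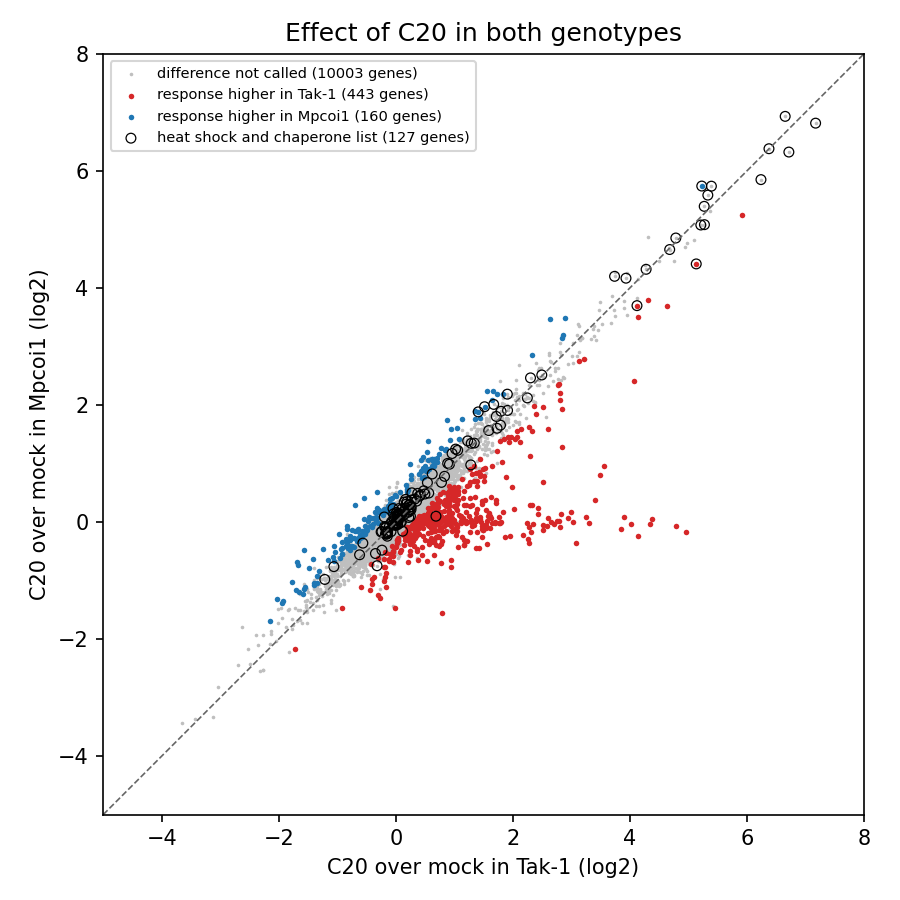
Each point is a tested gene, with its log2 change by C20 over mock in Tak-1 on the horizontal axis and in Mpcoi1 on the vertical axis. Red points are the 443 genes with a higher value in Tak-1, and blue points the 160 genes with a higher value in Mpcoi1, which includes larger falls in Tak-1. Grey points are the rest, and open circles the 127 heat shock and chaperone genes. Heat shock genes lie along the dashed line of equal change, while a group of red points with large rises in Tak-1 lies near 0 in Mpcoi1.

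In Mpcoi1, C20 moved many of the same heat shock, carbonic anhydrase and detoxification genes by similar amounts. HSP21 (Mapoly0045s0146) rose by 6.82 ± 0.10 (adjusted p = 1.3e-10), Mapoly0076s0004 by 6.93 ± 0.10 (adjusted p = 7.5e-11), MBF1C (Mapoly0105s0012) by 5.25 ± 0.10 and OPR1 (Mapoly0097s0082) by 4.15 ± 0.13. MBF1C rose by 0.67 less than in Tak-1, a called difference that was lost when some single arrays were left out. The alpha carbonic anhydrases Mapoly0012s0062, Mapoly0012s0068 and Mapoly0012s0070 were at -3.44, -3.37 and -3.33, and Mapoly0012s0065 was at -2.42. MpJAZ (Mapoly0097s0021) stood at 0.00 ± 0.10 (adjusted p = 0.99). Heat shock proteins and chaperones counted 68 rises and 14 falls among 127, 73 and 16 adjusted over the list alone (camera adjusted p = 1.3e-09; adjusted p = 0.0976 with an estimated correlation).

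The glutathione transferase and thiol redox list counted 31 rises and 5 falls among 76, 32 and 6 adjusted over the list alone (adjusted p = 0.00115; adjusted p = 0.0976 with an estimated correlation). Mapoly1812s0001 rose by 4.70 ± 0.08. WRKY and NAC factors counted 14 rises and 2 falls among 17, also when adjusted over the list alone (adjusted p = 2.2e-04; adjusted p = 0.209 with an estimated correlation). Proteasome and ubiquitin genes, which act in protein turnover, counted 47 rises and 10 falls among 129, also when adjusted over the list alone (adjusted p = 0.0184; adjusted p = 0.249 with an estimated correlation). The UFD1-type protein Mapoly0005s0132 rose by 3.19 ± 0.06 and BRIZ1 (Mapoly0007s0291) by 2.20 ± 0.06. In Tak-1 the same list had 41 rises and 12 falls, 38 and 12 adjusted over the list alone, without passing the list test (adjusted p = 0.136), and 28 and 34 with the value table.

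Peroxidases fell in Mpcoi1 more often than they rose, with 48 falls and 4 rises among 126, also when adjusted over the list alone. The camera adjusted p was 2.2e-05, and 0.588 with an estimated correlation. These ratios use the same mock Mpcoi1 channels in which many peroxidases were higher than in mock Tak-1, as given below, so the results are not independent. Of 100 cytochrome P450 genes, monooxygenases of hormone and secondary metabolism, 14 rose and 42 fell, 14 and 44 adjusted over the list alone (adjusted p = 0.00415; adjusted p = 0.437 with an estimated correlation). The CYP75B1 matches Mapoly0031s0060 and Mapoly0094s0036 rose by 2.34 ± 0.06 and 1.99 ± 0.05, and CYP707A3 (Mapoly0025s0085), a match to an abscisic acid hydroxylase, fell by 1.53. Cell wall genes counted 11 rises and 23 falls among 76, also when adjusted over the list alone (adjusted p = 0.0138; adjusted p = 0.209 with an estimated correlation).

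In all, 4431 of 10606 genes changed in Mpcoi1, 2515 up and 1916 down, and 513 rose and 134 fell at least 2-fold, against 5220 genes at an unadjusted p under 0.05. Agilent's log ratios gave 2061 up and 2790 down, 1960 and 3048 came from the value table, and median centring 1858 and 913, a total of 2771 genes. MpACT7 (Mapoly0016s0139) and MpEF1a (Mapoly0024s0116) stood at 0.17 ± 0.06 (adjusted p = 0.041) and 0.17 ± 0.05 (adjusted p = 0.026). Leaving out 1 array ended both calls. For MpACT7 these were Tak-1 replicates 1 and 4 and Mpcoi1 replicates 1, 2 and 4 (0.14 to 0.17), and for MpEF1a Mpcoi1 replicates 1 to 3 (0.15 to 0.16).

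**Figure D2:**
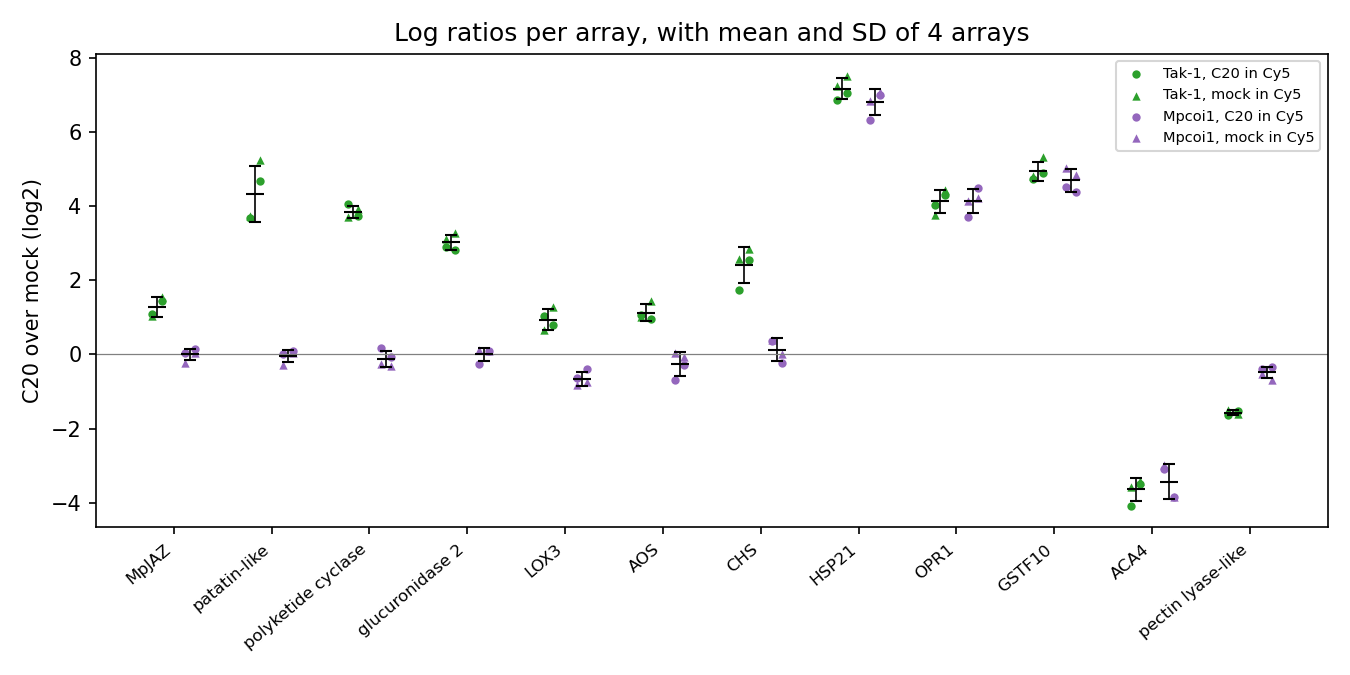
Log2 ratios of C20 over mock on each array for 12 genes in Tak-1 (green) and Mpcoi1 (purple); circles are arrays with C20 in Cy5, triangles arrays with mock in Cy5, and black bars the mean and SD of 4 arrays. MpJAZ, the patatin-like gene, the polyketide cyclase gene, glucuronidase 2 and CHS rose in Tak-1 and lie near 0 in Mpcoi1, while HSP21, OPR1, GSTF10 and ACA4 overlap between genotypes or nearly so.

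The response of a subset of genes differed between the genotypes, and the differences with the largest size were rises in Tak-1 that were absent or small in Mpcoi1. Slide row and culture coincided with genotype, so these differences cannot be assigned to genotype alone. MpJAZ (Mapoly0097s0021) rose in Tak-1 by 1.28 more than in Mpcoi1 (SE 0.13, adjusted p = 3.1e-04). The largest differences among described genes whose Tak-1 and Mpcoi1 arrays did not overlap were a patatin-like lipid acyl hydrolase (Mapoly0106s0023), which rose by 4.34 ± 0.22 in Tak-1 with a difference of 4.38 ± 0.32 (adjusted p = 2.7e-05), and a polyketide cyclase (Mapoly0021s0121). The latter rose by 3.86 ± 0.07 with a difference of 3.98 ± 0.11 (adjusted p = 1.6e-07). They were followed by an alpha carbonic anhydrase of another subgroup (Mapoly0060s0019, difference 3.31 ± 0.18), a cytochrome P450 matching CPD (Mapoly0033s0061, 3.04 ± 0.23), glucuronidase 2 (Mapoly0088s0001, 3.02 ± 0.09), an amino acid transporter (Mapoly0039s0036, 2.84 ± 0.11), a lipoxygenase-domain protein (Mapoly0106s0031, 2.77 ± 0.29) and the bHLH42 match Mapoly0028s0058 (2.74 ± 0.24). In Mpcoi1 these 8 genes stood between -0.12 and 0.37, none past the threshold. Mapoly0106s0023 was above background there on 1 of 4 arrays in either treatment, Mapoly0060s0019 on 2, and Mapoly0028s0058 on 0 mock and 1 C20 arrays, so their values in Mpcoi1 are near the detection limit. The other probe of glucuronidase 2 gave 1.64 in Tak-1 and -0.11 in Mpcoi1. Mapoly0033s0061 stood at 2.48 on Tak-1 replicate 4 and above 3.6 on the other Tak-1 arrays.

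Differences in the other direction were smaller. A pectin lyase-like gene (Mapoly0007s0096) fell by 1.57 in Tak-1 and by 0.49 in Mpcoi1, a difference of -1.08 ± 0.08 (adjusted p = 4.2e-05), and the sucrose transporter SUC4 (Mapoly0009s0099) fell by 1.70 and by 0.68 (difference -1.01 ± 0.15). A tonoplast intrinsic protein (Mapoly0004s0233), an aquaporin, fell by 1.67 and by 0.74 (difference -0.93 ± 0.11). A lipid transfer protein (Mapoly0120s0024) and the MYB16 match Mapoly0096s0058 were lower with C20 in Tak-1 (-0.55 ± 0.10 and -0.31 ± 0.10) and higher in Mpcoi1 (0.41 ± 0.10 and 0.51 ± 0.10), with differences of -0.96 ± 0.14 and -0.83 ± 0.15. The fall of Mapoly0096s0058 in Tak-1 was not called without replicate 1, 2 or 4 (-0.21 to -0.36). The receptor-like kinase match GSO1 (Mapoly0327s0001) rose by 0.56 ± 0.12 in Tak-1 and 1.38 ± 0.12 in Mpcoi1, and its difference of -0.82 ± 0.17 lost the call without Tak-1 replicate 1 (-0.77) or Mpcoi1 replicate 4 (-0.75). It was above background on 1 of 4 mock arrays in each genotype.

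Among the fixed lists, some oxylipin, phenylpropanoid and transport genes had a higher response in Tak-1. Here and below, a higher or lower response means the sign of the Tak-1 minus Mpcoi1 difference, so a larger fall in Tak-1 counts as lower. Of 21 oxylipin genes 7 had a higher response in Tak-1 and 0 a lower one, 9 and 0 adjusted over the list alone (camera adjusted p = 8.3e-07; adjusted p = 0.0596 with an estimated correlation). The lipoxygenase LOX3 (Mapoly0191s0014) rose by 0.94 ± 0.10 in Tak-1 and fell by 0.65 in Mpcoi1 (difference 1.59 ± 0.14). Allene oxide synthase (Mapoly0185s0014), an enzyme at the entry of jasmonate synthesis, rose by 1.13 ± 0.09 and was at -0.25 ± 0.09 in Mpcoi1 (difference 1.38 ± 0.12). Its Mpcoi1 value, between -0.29 and -0.14, lost the call without any of Tak-1 replicates 1 to 3 or Mpcoi1 replicates 2 to 4. ACX3 (Mapoly0007s0119) rose by 1.12 ± 0.07 with a difference of 1.03 ± 0.10. Of 53 phenylpropanoid and flavonoid enzymes 14 were higher and 1 lower, 16 and 1 adjusted over the list alone (adjusted p = 9.3e-06; adjusted p = 0.0596 with an estimated correlation). Differences of the chalcone synthase matches Mapoly0041s0118 and Mapoly0021s0159 were 2.29 ± 0.20 and 1.47 ± 0.12, and the other probe of the first gave 1.49 in Tak-1 and 0.02 in Mpcoi1. Of 37 transporters 5 were higher and 0 lower, 10 and 0 adjusted over the list alone (adjusted p = 0.0039; adjusted p = 0.116 with an estimated correlation). The MATE transporter Mapoly0005s0170 differed by 1.66 ± 0.11. Of 25 dirigent proteins 5 were higher and 0 lower, 7 and 0 adjusted over the list alone (adjusted p = 0.00304; adjusted p = 0.136 with an estimated correlation). Mapoly0062s0101 differed by 1.10 ± 0.09 and Mapoly0117s0015 by 0.94 ± 0.09.

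Of 100 P450 genes 14 were higher and 2 lower, 18 and 3 adjusted over the list alone (adjusted p = 0.00226; adjusted p = 0.412 with an estimated correlation). The CYP94D2 match Mapoly0023s0003 differed by 2.65 ± 0.17 and was above background on 3 mock and 2 C20 arrays of Mpcoi1, and its other probe gave 0.71 in Tak-1 and 0.02 in Mpcoi1. Of 40 abscisic acid response and LEA genes 7 were higher and 0 lower, 10 and 3 adjusted over the list alone (adjusted p = 0.0148; adjusted p = 0.116 with an estimated correlation). The LEA protein Mapoly0079s0020 differed by 0.72 ± 0.08. The peroxidase list passed its test upward (adjusted p = 0.0233; adjusted p = 0.724 with an estimated correlation) with 2 members called in either direction, also when adjusted over the list alone. Of these, the alpha-dioxygenase match Mapoly0089s0042, an oxylipin enzyme, differed by 1.03 ± 0.15. The test of the peroxidase list shares its mock channels with the mock comparison given below, so it is not independent of that result. Heat shock proteins had 3 members higher and 3 lower and glutathione transferases 2 and 1, also when adjusted over the list alone, without passing (adjusted p = 0.289 and 0.876). The HSP20-like Mapoly0075s0028 rose by 5.14 ± 0.06 in Tak-1 and 4.41 ± 0.06 in Mpcoi1 (difference 0.72 ± 0.09).

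Over all genes, 603 differed in response, 443 with a higher value in Tak-1 and 160 with a higher value in Mpcoi1, and 135 and 2 by log2 1 or more (1816 at an unadjusted p under 0.05). Of the 443, 401 rose in Tak-1, and of the 160, 92 fell in Tak-1, further than in Mpcoi1. Of the 651 genes that rose at least 2-fold in Tak-1, 550 (84.5%) also had a called rise of any size in Mpcoi1, against 154 if the lists were independent. Of the 651, 186 responded more in Tak-1, of which 85 were not called in Mpcoi1. All 172 genes that fell at least 2-fold in Tak-1 also had a called fall of any size in Mpcoi1, against 31.1 if independent. Only 134 genes fell at least 2-fold in Mpcoi1. The effects in both genotypes, which have separate mock samples, correlated across genes with Pearson's r of 0.884 and Spearman's rho of 0.804. Genes are not independent replicates. The count was 304 with median centring (214 and 90), 383 with scaling between arrays (309 and 74) and 349 at an adjusted p under 0.01 (299 and 50).

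In mock, some CAP and peroxidase genes were higher in Mpcoi1, and many genes with a higher C20 response in Tak-1 were lower. The cysteine-rich secretory CAP genes, a family that includes pathogenesis-related protein PR-1, led the higher values among described genes whose Tak-1 and Mpcoi1 arrays did not overlap. Mapoly0097s0005 was higher by 2.63 ± 0.39 (adjusted p = 5.1e-04), Mapoly0097s0003 by 2.53 ± 0.40, Mapoly0021s0004 by 2.38 ± 0.38 and Mapoly0590s0002 by 2.27 ± 0.40. In mock Tak-1 the first of these was above background on 1 of 4 arrays and the next on 2. Mapoly0097s0007, not well above background on any mock Tak-1 array, was 3.65-fold higher in Mpcoi1 by its brightest probe (limma adjusted p = 5.6e-03). On Mpcoi1 replicate 4 the log2 ratios of C20 over mock of these 5 CAP genes lay between 1.80 and 2.12, against -0.50 to 0.53 on the other Mpcoi1 arrays. Without that array their mock differences lay between 2.42 and 3.07. Their probes shared at most 43 of 60 bases. The peroxidases Mapoly0047s0007, Mapoly0047s0003 and Mapoly0004s0091 were higher by 2.21 ± 0.31, 1.61 ± 0.29 and 1.32 ± 0.17, with the first above background on 2 of 4 mock Tak-1 arrays.

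Lower in mock Mpcoi1 was the bHLH42 match Mapoly0028s0058, by 18.0-fold as measured, with no mock Mpcoi1 array above background (limma adjusted p = 1.4e-07). The patatin-like Mapoly0106s0023 (-2.35 ± 0.31) and the P450 Mapoly0033s0061 (-2.25 ± 0.23) were lower as well. A GDSL-type lipase (Mapoly0048s0056), which stood at 0.14 ± 0.10 and 0.08 ± 0.10 with C20, was lower by -2.23 ± 0.13 (adjusted p = 1.4e-07). A GH3 family gene (Mapoly0053s0073), whose family conjugates hormones to amino acids, was lower by -1.66 ± 0.15 and rose with C20 in Tak-1 by 2.30 ± 0.10 (difference 2.47 ± 0.14). Chlorophyllase 1 (Mapoly0008s0176) and the bHLH gene Mapoly0013s0167, not well above background in mock Mpcoi1, were 3.03-fold and 2.86-fold lower as measured (limma adjusted p = 4.0e-07 and 3.0e-05). A peptide transporter (Mapoly0095s0031) was lower by -1.51 ± 0.08. By its brightest probe, Mapoly0013s0167 rose with C20 by 4.07 ± 0.08 on the log2 scale in Tak-1 and 5.31-fold in Mpcoi1. The direction of its response difference (1.66 ± 0.12) turned with Agilent's ratios (-0.06). Its other probe gave 3.26 in Tak-1 and 0.99 in Mpcoi1. Of the 443 genes with a higher response in Tak-1, 142 (32.1%) were lower in mock Mpcoi1, against 4.07% of all tested genes; both comparisons use the same mock channels, so they are not independent.

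Of 126 peroxidases, 45 were higher and 4 lower in mock Mpcoi1, 68 and 6 adjusted over the list alone (camera adjusted p = 1.5e-10; adjusted p = 0.396 with an estimated correlation). Mapoly0064s0027 was at 0.96 ± 0.12 and Mapoly0004s0139 at -0.72 ± 0.08. The peroxidase results for C20 in Mpcoi1 and for the difference use the same mock Mpcoi1 channels, so they are not separate findings. Of 124 pathogenesis-related and defence genes, 22 were higher and 4 lower, 31 and 5 adjusted over the list alone (adjusted p = 1.7e-04; adjusted p = 0.396 with an estimated correlation). A basic chitinase (Mapoly0044s0030) was at 0.86 ± 0.11. Of 75 cell wall genes, 16 were higher and 2 lower, 26 and 4 adjusted over the list alone (adjusted p = 6.9e-04; adjusted p = 0.396 with an estimated correlation). The expansin EXPA14 (Mapoly0002s0243) was at 0.64 ± 0.13 and XTH15 (Mapoly0117s0020) at 0.57 ± 0.09. Some bHLH, AP2/ERF, WRKY and NAC genes were lower. Of the bHLH list, 0 of 31 bHLH genes were higher and 10 lower, 0 and 11 adjusted over the list alone (adjusted p = 2.0e-06; adjusted p = 0.0938 with an estimated correlation). The AMS match Mapoly0124s0021 was at -0.65 ± 0.07. Of 7 AP2/ERF genes 0 were higher and 2 lower, 0 and 4 adjusted over the list alone (adjusted p = 0.00806; adjusted p = 0.284 with an estimated correlation). RAP2.11 (Mapoly0038s0075) was at -0.50 ± 0.11 and ERF-1 (Mapoly0068s0088) at -0.63 ± 0.14. The response of Mapoly0068s0088 was higher in Tak-1 by 0.76 ± 0.14 here and lower with Agilent's ratios (-0.56), and it lost its call without Tak-1 replicate 1 or 3 (0.69 to 0.74). In mock it was above background on 3 of 4 Tak-1 and 1 of 4 Mpcoi1 arrays. Of 17 WRKY and NAC genes 0 were higher and 2 lower, 0 and 3 adjusted over the list alone (adjusted p = 0.0158; adjusted p = 0.323 with an estimated correlation). RD26 (Mapoly0035s0049) was at -1.20 ± 0.08. Of 53 phenylpropanoid enzymes 6 were higher and 9 lower, 8 and 10 adjusted over the list alone (adjusted p = 0.0158, downward; adjusted p = 0.396 with an estimated correlation). The chalcone synthase matches Mapoly0009s0178 and Mapoly0009s0180 were at -1.46 ± 0.20 and -1.02 ± 0.13.

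**Figure D3:**
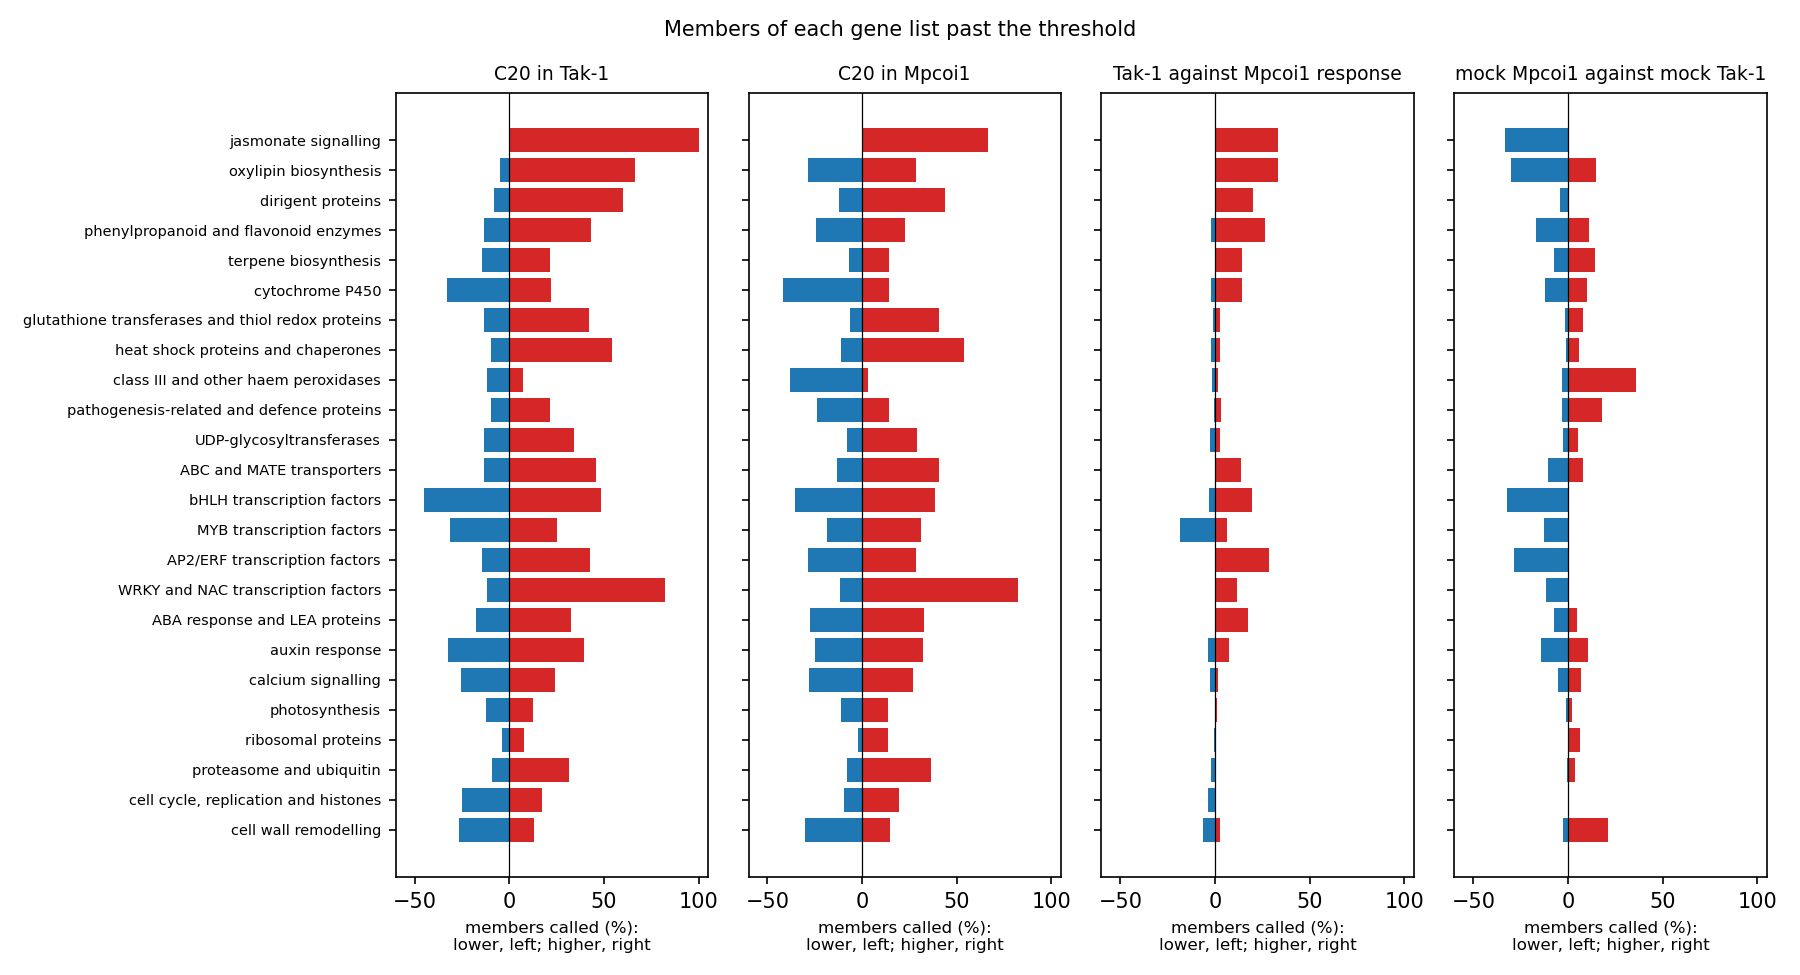
Share of the tested members of each gene list that passed the threshold, as percent of members, with higher members in red to the right of 0 and lower members in blue to the left, for the C20 effect in Tak-1, the C20 effect in Mpcoi1, the Tak-1 minus Mpcoi1 response and mock Mpcoi1 against mock Tak-1. Of the heat shock members, 69 of 127 rose in Tak-1 and 68 in Mpcoi1. A higher response in Tak-1 was called for 7 of 21 oxylipin and 14 of 53 phenylpropanoid members, and 45 of 126 peroxidases were higher in mock Mpcoi1. The balance of 19 of 100 pairs of list and comparison turned under another scaling, among them bHLH genes with C20.

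In total 1146 of 10542 genes differed in mock, 717 higher and 429 lower in Mpcoi1, and 26 and 50 by at least 2-fold (2702 at an unadjusted p under 0.05). Scaling the array means to a common median gave 541 higher and 528 lower. The genotypes were never on the same array, and all 4 Tak-1 arrays lay in a row of the slide and all 4 Mpcoi1 arrays in the other. Genotype, slide row and culture therefore cannot be told apart in this comparison or in the difference of C20 responses. The count fell to 758 without Tak-1 replicate 3, to 738 without Mpcoi1 replicate 1 and to 706 without Mpcoi1 replicate 4, and was 584 without the filter on dim probes, 735 with a replicate block, 513 at an adjusted p under 0.01 and 2163 with the mean of both channels.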

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

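Tests of ratio compression, dimness of the largest differences, dye, handling, shared probes, signal and slide row were written before their results were seen; those of dimness in general, of the offset and of a need for COI1 were chosen after the result was seen.

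The response to C20 differed between genotypes for 603 genes, by a test of the difference itself, and 57 named genes were among them. Differences are signed, so a larger fall in Tak-1 gives a value below 0. Larger responses in Tak-1 were found, in log2 units, for Mapoly0106s0023 (4.38), Mapoly0021s0121 (3.98), Mapoly0060s0019 (3.31), Mapoly0033s0061 (3.04), Mapoly0088s0001 (3.02), Mapoly0039s0036 (2.84), Mapoly0106s0031 (2.77) and Mapoly0028s0058 (2.74). In the same direction were Mapoly0028s0062 (2.68), Mapoly0023s0003 (2.65), Mapoly0053s0073 (2.47), Mapoly0041s0118 (2.29), Mapoly0108s0025 (1.72), Mapoly0013s0167 (1.66), Mapoly0005s0170 (1.66) and Mapoly0108s0042 (1.63). Also larger in Tak-1 were Mapoly0191s0014 (1.59), Mapoly0004s0163 (1.56), Mapoly0009s0178 (1.56), Mapoly0124s0021 (1.49), Mapoly0021s0159 (1.47), Mapoly0185s0014 (1.38), Mapoly0097s0021 (1.28) and Mapoly0062s0101 (1.10). A higher response in Tak-1 was further seen for Mapoly0089s0042 (1.03), Mapoly0007s0119 (1.03), Mapoly0107s0010 (1.02), Mapoly0008s0176 (1.01), Mapoly0117s0013 (0.94), Mapoly0117s0015 (0.94), Mapoly0009s0180 (0.78) and Mapoly0068s0088 (0.76). Smaller differences upward were those of Mapoly0075s0028 (0.72), Mapoly0079s0020 (0.72), Mapoly0105s0012 (0.67), Mapoly0874s0001 (0.65), Mapoly0197s0014 (0.59), Mapoly0035s0049 (0.47), Mapoly0031s0060 (0.43) and Mapoly0098s0046 (0.41). The remaining genes with a higher response were Mapoly0094s0036 (0.38), Mapoly0095s0031 (0.33) and Mapoly0169s0009 (0.30). The C20 value was lower in Tak-1 than in Mpcoi1, which includes larger falls in Tak-1, for Mapoly0007s0096 (-1.08), Mapoly0009s0099 (-1.01), Mapoly0120s0024 (-0.96), Mapoly0004s0233 (-0.93), Mapoly0096s0058 (-0.83), Mapoly0040s0117 (-0.83), Mapoly0327s0001 (-0.82) and Mapoly0031s0032 (-0.59). The other genes with a lower value in Tak-1 were Mapoly0004s0080 (-0.52), Mapoly0076s0005 (-0.51), Mapoly0007s0080 (-0.45), Mapoly0010s0211 (-0.43), Mapoly0007s0291 (-0.37) and Mapoly0005s0132 (-0.33). Not all of these directions are settled, since the Tak-1 rise of Mapoly0031s0032 and the Mpcoi1 rise of Mapoly0013s0167 rest on mock signals that were above background on 0 arrays, and the differences of Mapoly0013s0167 and Mapoly0068s0088 turned with Agilent's ratios (-0.059 and -0.56). Mapoly0028s0058 and Mapoly0008s0176 were above background on 0 mock arrays of Mpcoi1.

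Leaving out 1 array ended the call of the difference for 15 named genes, as follows. The call was lost for Mapoly0004s0080 without replicate Tak-1 2 or Mpcoi1 1, 3 or 4 (-0.52 to -0.48) and Mapoly0005s0132 without replicate Tak-1 1, 2, 3 or 4 or Mpcoi1 1, 2 or 3 (-0.36 to -0.28). Likewise it was lost for Mapoly0007s0291 without replicate Tak-1 1, 2 or 4 or Mpcoi1 1, 2, 3 or 4 (-0.39 to -0.30) and Mapoly0010s0211 without replicate Tak-1 1, 3 or 4 or Mpcoi1 1, 3 or 4 (-0.46 to -0.36). The same held for Mapoly0031s0032 without replicate Tak-1 2 (-0.55) and Mapoly0031s0060 without replicate Tak-1 1 or 3 (0.39 to 0.41). Further cases were Mapoly0035s0049 without replicate Tak-1 1 or 3 or Mpcoi1 3 (0.44 to 0.46) and Mapoly0068s0088 without replicate Tak-1 1 or 3 (0.69 to 0.74). It also ended for Mapoly0094s0036 without replicate Tak-1 3 or Mpcoi1 4 (0.33 to 0.36) and Mapoly0095s0031 without replicate Tak-1 1, 2, 3 or 4 or Mpcoi1 1, 3 or 4 (0.29 to 0.37). Calls were lost too for Mapoly0098s0046 without replicate Tak-1 2 or 3 (0.38 to 0.39) and Mapoly0105s0012 without replicate Tak-1 1, 3 or 4 or Mpcoi1 1 (0.63 to 0.68). Others were Mapoly0117s0013 without replicate Tak-1 1, 3 or 4 or Mpcoi1 1 or 3 (0.76 to 0.95) and Mapoly0169s0009 without any of the 8 arrays (0.27 to 0.33). The last was Mapoly0327s0001 without replicate Tak-1 1 or Mpcoi1 4 (-0.77 to -0.75).

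Some arrays lay far from the other 3 of their group for 15 of 261 groups of 4 ratios, where 13.05 would be expected by chance, so none of them was left out. In Tak-1, Mapoly0045s0084 was at 4.91 on replicate 2 against 5.29 to 5.33 on the others, and Mapoly0012s0063 was at -3.14 on replicate 2 against -2.57 to -2.48 on the others. Mapoly0048s0056 was at 0.47 on replicate 2 against 0.01 to 0.05 on the others, and Mapoly0040s0117 was at 3.02 on replicate 3 against 2.48 to 2.53 on the others. Mapoly0033s0061 was at 2.48 on replicate 4 against 3.63 to 3.79 on the others. In Mpcoi1, Mapoly0079s0053 was at 0.89 on replicate 1 against 0.62 to 0.66 on the others, and Mapoly0020s0097 was at -1.42 on replicate 2 against -2.10 to -2.08 on the others. Mapoly0088s0001 was at -0.25 on replicate 2 against 0.08 to 0.11 on the others, and Mapoly0095s0031 was at -0.11 on replicate 2 against -0.40 to -0.37 on the others. Mapoly0075s0028 was at 4.26 on replicate 2 against 4.46 to 4.47 on the others, and Mapoly0023s0003 was at 0.15 on replicate 2 against -0.26 to -0.20 on the others. Mapoly0106s0031 was at 0.20 on replicate 3 against -0.05 to -0.02 on the others, and Mapoly0038s0075 was at -0.69 on replicate 3 against -0.23 to -0.15 on the others. Mapoly0025s0025 was at -0.52 on replicate 4 against 0.02 to 0.09 on the others, and Mapoly0004s0163 was at -0.00701 on replicate 4 against -0.22 on the others.

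The surplus of genes with a higher C20 value in Tak-1 (443 against 160, by the sign of the difference) was set against technical causes. The slope of the Mpcoi1 effect on the Tak-1 effect over heat shock genes was 0.998 (0.973 to 1.03, from resampling genes). It argues against an equal compression of all ratios on Mpcoi1 arrays, provided that heat shock genes respond alike in both genotypes. Large rises weigh most in this slope, so compression of dim genes alone was not tested. Against dimness as the whole cause, 71.3% (67.4% to 75.0%) of the called genes above background in both genotypes had the higher value in Tak-1. The intervals of this share and of those below treat genes as independent, which they are not. They do not measure the spread between replicates. Of the 135 largest differences, 108 (80%, 72.3% to 86.4%) were above background on at least 3 Mpcoi1 arrays, and for the other 27 dimness may contribute. Shrinkage by the offset as the whole cause was set against Agilent's ratios, which add no offset, and these argued against it. With Agilent's ratios, 293 of 409 called genes without surrogate values (71.6%, 67% to 76.0%) had the higher value in Tak-1. For 33 of the largest differences, whose Agilent ratios hold surrogate values, shrinkage cannot be told apart from a response. A need for COI1 stays open, because MpJAZ (1.28, 1.01 to 1.55) is itself one of the 443 genes. Slide row and culture, which coincide with genotype, stay open as well.

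Of 127 heat shock genes 69 rose in Tak-1 and 68 in Mpcoi1 (camera adjusted p = 1.4e-07 and 1.3e-09; adjusted p = 0.149 and adjusted p = 0.0976 with an estimated correlation). The lowest of the medians over the 69 risers in the 4 sets of genotype and dye was 1.19, in Tak-1 with mock in Cy5. The risers were chosen by their call in Tak-1, so only the Mpcoi1 sets could test dye bias. Their medians of 1.34 with C20 in Cy5 and 1.20 with mock in Cy5 argue against it. The 69 risers rose by a median of 1.25 in Mpcoi1 as well, with a median difference of -0.0552 (-0.0867 to 0.00266, from resampling genes) between genotypes. This argues against a need for COI1 for the risers as a set, not for each member. In the list, 3 members had a higher response in Tak-1 and 3 a lower one. The slope over heat shock genes above assumes such a likeness, so neither result backs the other. Handling of plants at treatment cannot be told from the compound, because the median rise of 1.25 in Mpcoi1 would follow from either.

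Of 126 peroxidase genes 45 were higher and 4 lower in mock Mpcoi1 (camera adjusted p = 1.5e-10; adjusted p = 0.396 with an estimated correlation). Near-identical probes were excluded as the whole cause, as the 45 higher members formed 40 groups of probes, linked by at least 50 of 60 shared bases. The largest group held 3 probes, and up to 60 of 60 bases were shared. Probes were not compared with the transcripts of other members, so signal from related transcripts stays possible. A shift that depends on signal was excluded by a median of 0.0488 (0.0341 to 0.0584) for genes of matched signal, against 0.438 for the list. Slide row and growth of the plants may explain the shift of 0.438 as well as genotype, since the design does not separate them.

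For chance, of 34 splits of the arrays that kept the dye term, those other than the real split gave at most 1 gene for the difference and 0 in mock, against 603 and 1146. No other split gave as many genes, which is the smallest share that 34 splits allow. Splits that mix the genotypes turn any difference between them into spread, which lowers their counts. A difference of slide row or culture would do the same. The split that follows the dye could not be fitted with the dye term and without it called 858 genes. For C20 in each genotype the 8 sign patterns of 4 arrays are too few for a share under 0.05.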

How the results depend on the processing

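The number of genes changed by C20 in Tak-1 stayed within 1.5 times of 4633 under every alternative, from 3505 at an adjusted p under 0.01 to 5576 with the value table. In Mpcoi1 the count fell from 4431 to 2771 with median centring. The 603 genes with a genotype difference became 304 with median centring, 383 with scaling between arrays and 349 at an adjusted p under 0.01, and 558 among genes above background in both genotypes, a filter chosen after seeing the data. The 1146 genes of the mock comparison became 2163 with the mean of both channels, 584 without the filter on dim probes, 735 with a replicate block and 513 at an adjusted p under 0.01, and lay between 706 (without Mpcoi1 replicate 4) and 1113 (without Tak-1 replicate 4) with 1 array left out, with 758 without Tak-1 replicate 3 and 738 without Mpcoi1 replicate 1; with genes above background in mock of both genotypes, also chosen after seeing the data, it was 1137. A stricter threshold calls fewer genes by construction; for the other counts the cause was not tested.

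Of the tested values of the named genes, the difference turned its direction with Agilent's ratios for Mapoly0013s0167 (-0.059 against 1.66) and Mapoly0068s0088 (-0.56 against 0.76), both dim in mock Mpcoi1; the cause was not tested. No other named value that was called in either setting turned. Signs of values called in neither setting were not compared. Recomputed values kept their side of the threshold, and where called their direction, in 1302 cases for the difference and 844 in mock. In Mpcoi1 and Tak-1 these were 2198 and 2654. The call was lost in 160, 58, 63 and 30 cases for the difference, mock, Mpcoi1 and Tak-1. The correlation of effects between genotypes was 0.893 over genes called in Tak-1 and 0.864 with Agilent's ratios. With median centring the log2 median of all genes was -0.16 for the difference, against -0.01 with loess.

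Replicates with the same number in both genotypes correlated in their deviations with r of 0.305, 0.287, 0.359 and 0.458 for numbers 1 to 4, and with 0.0322, -0.249, -0.0197 and 0.000167 after removal of dye. With the dye term fitted, the consensus correlation of arrays with the same number was 0.0431. Removing a dye term shared by both genotypes lowers the r values, so values near 0 do not settle whether the numbers pair samples. A fixed block gave 4657, 4459, 556 and 735 genes in Tak-1, Mpcoi1, the difference and mock, and a random block 4624, 4409 and 631. Signal over background limits what can be seen: 10606 of 19217 genes were bright enough to test.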

Other observations

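Some genes of calcium binding, light stress and auxin response moved with C20. The EF-hand proteins Mapoly0045s0017 and Mapoly0045s0019 rose by 3.52 ± 0.09 and 2.73 ± 0.07 in Tak-1 and by 3.38 and 2.64 in Mpcoi1. The early light-induced protein Mapoly0047s0106, which protects chlorophyll under light stress, rose by 3.95 ± 0.10 and 4.25 ± 0.10, whereas Mapoly0004s0163 of the same family rose by 1.40 ± 0.07 in Tak-1 and was at -0.17 ± 0.07 in Mpcoi1. The latter was above background on 2 of 4 mock arrays of Tak-1 and 2 of 4 C20 arrays of Mpcoi1. The glycosyltransferase matches Mapoly0008s0244 and Mapoly0092s0015 rose by 2.60 and 2.06 in Tak-1 and by 2.33 and 2.43 in Mpcoi1. Among auxin genes, the SAUR genes Mapoly0002s0085 and Mapoly0035s0025 moved by 2.82 ± 0.09 and -2.02 in Tak-1 and by 2.42 and -1.72 in Mpcoi1. The ethylene response factor Rap2.6L (Mapoly0166s0010) rose by 3.42 ± 0.14 in Tak-1, without a called difference from Mpcoi1. The MYB117 match Mapoly0008s0029 rose by 1.92 in Tak-1 and 1.76 in Mpcoi1, the cupin Mapoly0134s0025 by 3.19 ± 0.05 and 3.14, and the replication protein Mapoly0076s0016 by 1.26 and 1.33.

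Phenylpropanoid and terpene genes were divided. Cinnamate 4-hydroxylase (Mapoly0041s0103) fell by 1.18 in Tak-1 and 1.19 in Mpcoi1, while the HCT match Mapoly0107s0010 rose by 2.61 ± 0.10 and 1.59 ± 0.10 and the 4CL1 match Mapoly0197s0014 by 1.06 and 0.47. The terpenoid cyclases Mapoly0108s0025 and Mapoly0108s0042 rose by 1.62 and 1.49 in Tak-1 and were at -0.10 and -0.13 in Mpcoi1. They were above background in mock Tak-1 on 3 and 2 of 4 arrays. The bHLH42 matches Mapoly0028s0062 and Mapoly0098s0046 rose by 3.49 ± 0.18 and 1.79 in Tak-1 and by 0.81 and 1.38 in Mpcoi1. Another probe of Mapoly0028s0062 gave 1.94 in Tak-1 and 0.38 in Mpcoi1. The MYB84 match Mapoly0874s0001 was at -0.05 in Tak-1 and fell by 0.69 in Mpcoi1, and the histone genes Mapoly0007s0080 and Mapoly0010s0211 fell by 0.38 and 0.34 in Tak-1 and were at 0.07 and 0.09 in Mpcoi1. The ribosomal proteins Mapoly0003s0247 and Mapoly0136s0019 moved by 1.08 and -1.14 in Tak-1 and by 1.13 and -0.92 in Mpcoi1. MpMYB02 (Mapoly0006s0226), a factor of oil body cells, was at 0.17 and 0.03 and passed in neither.

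Lists that did not pass in Tak-1 are given as members that rose and fell. Phenylpropanoid and flavonoid enzymes had 23 and 7 of 53, 23 and 8 adjusted over the list alone (adjusted p = 0.136), and terpene biosynthesis had 3 and 2 of 14, turned by Agilent's ratios to 3 and 4 and the value table to 3 and 6 (adjusted p = 0.978). Cytochrome P450 had 22 and 33 of 100 (adjusted p = 0.319), and pathogenesis-related and defence proteins had 27 and 12 of 125, 26 and 12 adjusted over the list alone, turned by the value table to 23 and 28 (adjusted p = 0.749). UDP-glycosyltransferases had 13 and 5 of 38 (adjusted p = 0.385), and bHLH transcription factors had 15 and 14 of 31, turned by Agilent's ratios to 14 and 15 and median centring to 12 and 14 and the value table to 13 and 14 (adjusted p = 0.718). MYB transcription factors had 4 and 5 of 16, 4 and 6 adjusted over the list alone (adjusted p = 0.784), and AP2/ERF transcription factors had 3 and 1 of 7 (adjusted p = 0.495). ABA response and LEA proteins had 13 and 7 of 40, 13 and 8 adjusted over the list alone (adjusted p = 0.588), and auxin response had 11 and 9 of 28, turned by median centring to 8 and 9 and the value table to 8 and 10 (adjusted p = 0.718). Calcium signalling had 18 and 19 of 75 (adjusted p = 0.617), and photosynthesis had 12 and 12 of 97, 10 and 7 adjusted over the list alone (adjusted p = 0.617). Ribosomal proteins had 14 and 7 of 175, 4 and 2 adjusted over the list alone, turned by Agilent's ratios to 7 and 20 and median centring to 3 and 10 and scaling between arrays to 6 and 7 and the value table to 7 and 44 (adjusted p = 0.889), and cell cycle, replication and histones had 9 and 13 of 52, 8 and 13 adjusted over the list alone (adjusted p = 0.617). Antheridium and motile sperm markers had 1 and 2 of 3 (adjusted p = 0.542). Counts adjusted over the list alone were the same where none are given.

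Lists that did not pass in Mpcoi1 are given in the same way. Jasmonate signalling had 2 and 0 of 3 (adjusted p = 0.333), and oxylipin biosynthesis had 6 and 6 of 21 (adjusted p = 0.892). Dirigent proteins had 11 and 3 of 25, 11 and 4 adjusted over the list alone (adjusted p = 0.137), and phenylpropanoid and flavonoid enzymes had 12 and 13 of 53, 12 and 15 adjusted over the list alone, turned by median centring to 10 and 5 (adjusted p = 0.594). Terpene biosynthesis had 2 and 1 of 14, turned by Agilent's ratios to 1 and 4 and the value table to 1 and 3 (adjusted p = 0.611), and pathogenesis-related and defence proteins had 18 and 30 of 125, turned by median centring to 22 and 19 (adjusted p = 0.333). UDP-glycosyltransferases had 11 and 3 of 38 (adjusted p = 0.288), and ABC and MATE transporters had 15 and 5 of 37, 16 and 6 adjusted over the list alone (adjusted p = 0.0738). bHLH transcription factors had 12 and 11 of 31, 13 and 11 adjusted over the list alone, turned by Agilent's ratios to 12 and 13 and the value table to 11 and 13 (adjusted p = 0.896), and MYB transcription factors had 5 and 3 of 16 (adjusted p = 0.83). AP2/ERF transcription factors had 2 and 2 of 7 (adjusted p = 0.689), and ABA response and LEA proteins had 13 and 11 of 40, 13 and 13 adjusted over the list alone, turned by Agilent's ratios to 12 and 14 and the value table to 12 and 16 (adjusted p = 0.689). Auxin response had 9 and 7 of 28, 10 and 7 adjusted over the list alone, turned by Agilent's ratios to 8 and 9 and the value table to 7 and 8 (adjusted p = 0.83), and calcium signalling had 20 and 21 of 75, 21 and 21 adjusted over the list alone, turned by median centring to 16 and 8 (adjusted p = 0.779). Photosynthesis had 13 and 11 of 97, 12 and 8 adjusted over the list alone, turned by Agilent's ratios to 11 and 12 and the value table to 14 and 26 (adjusted p = 0.513), and ribosomal proteins had 24 and 4 of 175, 9 and 1 adjusted over the list alone, turned by the value table to 10 and 22 (adjusted p = 0.577). Cell cycle, replication and histones had 10 and 5 of 52, 9 and 5 adjusted over the list alone, turned by Agilent's ratios to 5 and 7 and the value table to 5 and 7 (adjusted p = 0.513), and antheridium and motile sperm markers had 1 and 2 of 3 (adjusted p = 0.577).

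Lists that did not pass for the difference are given as members with a higher and a lower response in Tak-1. Jasmonate signalling had 1 and 0 of 3 (adjusted p = 0.115), and terpene biosynthesis had 2 and 0 of 14 (adjusted p = 0.529). Pathogenesis-related and defence proteins had 4 and 1 of 125 (adjusted p = 0.0816), and UDP-glycosyltransferases had 1 and 1 of 38, 1 and 0 adjusted over the list alone (adjusted p = 0.927). bHLH transcription factors had 6 and 1 of 31, 6 and 7 adjusted over the list alone (adjusted p = 0.652), and MYB transcription factors had 1 and 3 of 16, 2 and 4 adjusted over the list alone (adjusted p = 0.491). AP2/ERF transcription factors had 2 and 0 of 7 (adjusted p = 0.205), and WRKY and NAC transcription factors had 2 and 0 of 17, 3 and 1 adjusted over the list alone (adjusted p = 0.529). Auxin response had 2 and 1 of 28, 2 and 2 adjusted over the list alone (adjusted p = 0.876), and calcium signalling had 1 and 2 of 75 (adjusted p = 0.653). Photosynthesis had 1 and 0 of 97 (adjusted p = 0.927), and ribosomal proteins had 0 and 1 of 175 (adjusted p = 0.529). Proteasome and ubiquitin had 0 and 3 of 129, 0 and 0 adjusted over the list alone (adjusted p = 0.244), and cell cycle, replication and histones had 0 and 2 of 52 (adjusted p = 0.0816). Cell wall remodelling had 2 and 5 of 76 (adjusted p = 0.876), and antheridium and motile sperm markers had 0 and 0 of 3 (adjusted p = 0.876).

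Lists that did not pass in mock are given as members higher and lower in Mpcoi1. Jasmonate signalling had 0 and 1 of 3 (adjusted p = 0.136), and oxylipin biosynthesis had 3 and 6 of 20, 5 and 7 adjusted over the list alone (adjusted p = 0.436). Dirigent proteins had 0 and 1 of 24 (adjusted p = 0.665), and terpene biosynthesis had 2 and 1 of 14, 5 and 1 adjusted over the list alone, turned by the mean of both channels to 3 and 4 (adjusted p = 0.7). Cytochrome P450 had 10 and 12 of 99, 15 and 12 adjusted over the list alone (adjusted p = 0.665), and glutathione transferases and thiol redox proteins had 6 and 1 of 76 (adjusted p = 0.665). Heat shock proteins and chaperones had 7 and 1 of 125 (adjusted p = 0.171), and UDP-glycosyltransferases had 2 and 1 of 37, 1 and 1 adjusted over the list alone (adjusted p = 0.639). ABC and MATE transporters had 3 and 4 of 37, 3 and 6 adjusted over the list alone (adjusted p = 0.201), and MYB transcription factors had 0 and 2 of 16 (adjusted p = 0.073). ABA response and LEA proteins had 2 and 3 of 40, 5 and 3 adjusted over the list alone, turned by Agilent's signals to 5 and 3 and the mean of both channels to 6 and 5 (adjusted p = 0.75), and auxin response had 3 and 4 of 28, 4 and 6 adjusted over the list alone (adjusted p = 0.102). Calcium signalling had 5 and 4 of 73 (adjusted p = 0.84), and photosynthesis had 2 and 1 of 96, turned by a common median to 2 and 4 (adjusted p = 0.84). Ribosomal proteins had 11 and 0 of 175, 2 and 0 adjusted over the list alone (adjusted p = 0.287), and proteasome and ubiquitin had 5 and 1 of 129, 2 and 1 adjusted over the list alone (adjusted p = 0.487). Cell cycle, replication and histones had 0 and 0 of 51 (adjusted p = 0.665), and antheridium and motile sperm markers had 0 and 0 of 3 (adjusted p = 0.84).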
